A study of Mus musculus with 6 samples.

How the data were processed

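Gene expression was measured in mouse bone marrow pre-B cells that carry floxed Ppp2r1a alleles, the gene of the scaffold subunit of protein phosphatase 2A (PP2A), and that had been transduced with the BCR-ABL1 oncogene. Per the labels, the cells were then transduced with Cre recombinase, which deletes the floxed gene, or with an empty vector (EV). Total RNA was extracted with a Qiagen RNeasy kit, and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays, per the labels' protocols. There were 3 Cre arrays and 3 EV arrays, and each array was assigned to its group by its title. The titles number the arrays of each group as repeats. They do not say whether repeats came from separate cultures or mice, so p-values measure the spread between these arrays, which may be technical. How long after Cre transduction the cells were collected is not given in the sources used here.

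The values are log2 expression levels, 1 per probe set and array, as deposited by the authors. They were made with RMA (background correction, quantile normalization and summary of the probes), per the submitters' processing notes. The RMA version and the probe annotation are not given in the sources used here. The range and near-equal quantiles of the arrays were checked on the values: array medians lay between 5.22 and 5.27, and levels between 1.22 and 13.47. Quantile normalization sets the arrays to one distribution, so a change of the whole transcriptome cannot be seen in these values and every change is relative to the other genes. No detection calls were used, and a gene near the lower end of the range has a log2 change that understates its fold change. For an array study of this size the number of arrays limits the precision.

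Of 25006 probes, 21467 were assigned to 1 gene symbol, 1521 to several and 2018 to none. The assignments came from the platform annotation, and 21386 of the probes with 1 symbol were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes only. Probes with several genes or none were kept out of the main test. For the 931 genes with several probes the probe with the highest mean over all 6 arrays was taken, which left 19733 genes.

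Genes were compared between Cre and EV with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the factor, no block, no filter on dim probes). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p below 0.05, with no fold minimum. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Values are given as means ± SD of 3 arrays on the log2 scale, and changes as Cre minus EV with the standard error (SE) of limma's moderated fit. Before the data were examined, 37 gene lists were fixed, covering metabolism, signalling, cell cycle, stress, cell death and markers of B cell stages and of other cell types. Of their 944 entries, 863 were matched to a tested gene (796 distinct genes). Another 27 shared a probe with other genes and 54 had no probe here. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 37 lists. A list was said to move at an adjusted p below 0.05.

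The genes named in the text were chosen by a rule that was also fixed before the data were examined: Ppp2r1a, the 12 largest rises and the 12 largest falls among genes that passed the test with no overlap between groups, and up to 4 members of each list with the smallest p among those that passed. Where fewer than 2 members passed, the 2 with the smallest p were taken, and are given as values. Predicted genes, small RNAs, olfactory and vomeronasal receptors and single antigen receptor segments were skipped when the largest changes were named. Pdk1, Tpi1, Pfkl, Ldha, Bnip3l, Ak4, Spib, Vav2, Igf1r, Slc2a6, Atf5, Vpreb1, Il7r, Pgd, Tkt, Nqo1 and Cask were named after their values were seen. So were Ighm, the sex-linked genes, the Hoxa, Slamf and Snora genes other than Hoxa5, and the abundant mature B transcripts in the closing section.

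The test was tried on simulated data built from the Cre against EV comparison of 19733 genes, with 100 changed genes of each size. Noise was drawn once and independently for each gene, and the SDs were shuffled among genes. The simulation therefore lacks correlation between genes and the link of spread to level. It recovered 47% of changes of 0.5 log2 and 95% of changes of 1 log2. Of its calls, 3.4% were genes that had not been changed, and 0 genes were called in data with no change. As far as the real noise behaves like this, changes of about 0.5 log2 or less can often be missed with 3 arrays per group. Alternatives fixed beforehand were the repeat number as a block, quantile normalization again, median centring, leaving out the lowest 25% or 50% of genes by mean level, eBayes with trend and robust settings, ordinary t statistics, array weights, the mean of all probes of a gene, all probes, a 2-fold minimum, limma's treat against a 1.2-fold change, leaving out each array in turn, camera with an estimated correlation, and fry. Lists with some members left out were added after the results were seen.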

Results

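Expression was profiled on 6 arrays of mouse pre-B cells transformed with BCR-ABL1, a fusion kinase that drives B cell acute lymphoblastic leukaemia. In 3 of them the cells had received Cre, which deletes the floxed gene of the PP2A scaffold subunit, and in 3 an empty vector (EV). The series asks how loss of PP2A bears on survival and redox balance of malignant pre-B cells, so the design holds a single comparison, Cre against EV. None of the 6 arrays had Cre in cells without floxed alleles. Effects of Cre itself therefore cannot be told apart from loss of Ppp2r1a in any result below. Arrays of the same group correlated across genes with r between 0.9955 and 0.9963, and arrays of different groups with r between 0.9913 and 0.9923. The first principal component held 48.3% of the variance and separated Cre from EV, and the second held 14.4%.

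Ppp2r1a, the deleted gene, fell 4.15-fold in the Cre cells. Its probe set (10442155, chromosome 17) read 7.12, 6.98 and 6.92 in the Cre arrays and 9.06, 9.05 and 9.06 in the EV arrays, a log2 change of -2.05 (SE 0.07; limma adjusted p = 1.203e-05). The probe set summarises the gene as a whole, so signal from exons outside the deleted part may remain in the Cre value. Whether transduced cells were selected is not given in the sources used here. Cells that kept the gene may therefore also add to that value. Of 19 PP2A subunits measured, Ppp2r1a was the 1 member that passed the test, also when adjusted over the list alone. Ppp2r2d, a regulatory B subunit, had the next smallest p and differed by 0.17 (SE 0.07; adjusted p = 0.266). The subunit list did not move as a whole (camera adjusted p = 0.948), and its median change of 0.01 and its mean of -0.10 had opposite signs. None of 18 PP2A regulators and related phosphatases passed (adjusted over the list alone, 2 rose and 1 fell; camera adjusted p = 0.311). Igbp1, which binds the free catalytic subunit, differed by -0.28 (SE 0.07; adjusted p = 0.088), and Cip2a, a PP2A inhibitor, by 0.32 (SE 0.08; adjusted p = 0.093).

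Beyond the deleted gene, 13 of 22 glycolysis genes and 10 of 24 hypoxia targets fell in the Cre cells, as did Mt1 and Mt2, metallothioneins, and Rag1 and Rag2, the V(D)J recombinase, while 5 of 27 mature B markers rose. Camera called these lists with its preset correlation only: the adjusted p was 0.147 for glycolysis, 0.254 for hypoxia and 0.147 for mature B markers with an estimated correlation. Of 19733 genes, 267 rose and 422 fell at a limma adjusted p below 0.05 (689 genes, 3.49%), and 128 of them changed at least 2-fold. The median size of the changes that passed was 0.56 on the log2 scale. The Cre and EV arrays did not overlap for 4441 genes (22.5%), against 10% by chance, and for all 689 that passed. Leaving out any 1 of the 6 arrays lowered the count to between 362 (without EV replicate 2) and 424 (without EV replicate 3). Of the 105 named genes that passed, Ppp2r1a apart, 60 also passed in all 6 of those fits.

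The largest rise was that of Stag3, a meiotic cohesin subunit, which went from 4.10 ± 0.21 in EV to 7.57 ± 0.09 in Cre (SD, n = 3), 11.0-fold, at a limma adjusted p of 1.146e-05. Dzip1, a ciliary protein, rose by 2.33 (SE 0.07), and Tspan6, a tetraspanin, by 2.06 (SE 0.23). Akr1c12, an aldo-keto reductase, rose by 2.01 (SE 0.19), and Lrrtm2, a leucine-rich repeat protein, by 1.99 (SE 0.18). Surface markers were among the 12 largest rises: Ly6f rose by 1.82 (SE 0.11), Ly6d, a marker of B lineage commitment, by 1.74 (SE 0.08), and Cd74, the MHC class II invariant chain, by 1.64 (SE 0.08). The others were Rpgr (1.78, SE 0.16), Zfp182 (1.78, SE 0.12), Hoxa5 (1.77, SE 0.16) and Chic1 (1.72, SE 0.16). Tspan6, Rpgr, Zfp182 and Chic1 are X-linked, and Xist differed by -0.05 (SE 0.06). In EV, Stag3, Dzip1, Tspan6, Akr1c12, Lrrtm2, Rpgr, Zfp182, Hoxa5 and Chic1 read between 3.14 and 4.98, below the array medians, so their folds rest on a dim baseline.

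The largest fall was that of Gdpd3, a lysophospholipase D, from 9.66 ± 0.03 in EV to 4.03 ± 0.06 in Cre (SD, n = 3), 49.3-fold, at a limma adjusted p of 1.714e-08. Kynu, the kynureninase of tryptophan breakdown, fell 12.5-fold, Ppic, a cyclophilin, 11.4-fold, and Ly86, the partner of the Toll-like receptor homologue Cd180, 11.2-fold. The metallothioneins Mt1 and Mt2, which bind zinc and copper, fell 7.89-fold and 7.27-fold. Gstt2, a glutathione transferase, fell 5.38-fold, and the long non-coding RNA Firre 8.51-fold. Prr13 fell 6.26-fold, the homeobox gene En2 5.07-fold and the Hippo pathway transcription factor Tead1 4.72-fold. Rag1, which cuts DNA in V(D)J recombination, fell 4.27-fold. In Cre, Gdpd3, Ly86, Prr13, Ppic, Firre, Kynu and Tead1 read between 4.03 and 5.22, below the medians of the Cre arrays, so their folds rest on a dim Cre level. All 24 of these largest changes passed the threshold in each fit with 1 array left out.

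**Figure D1:**
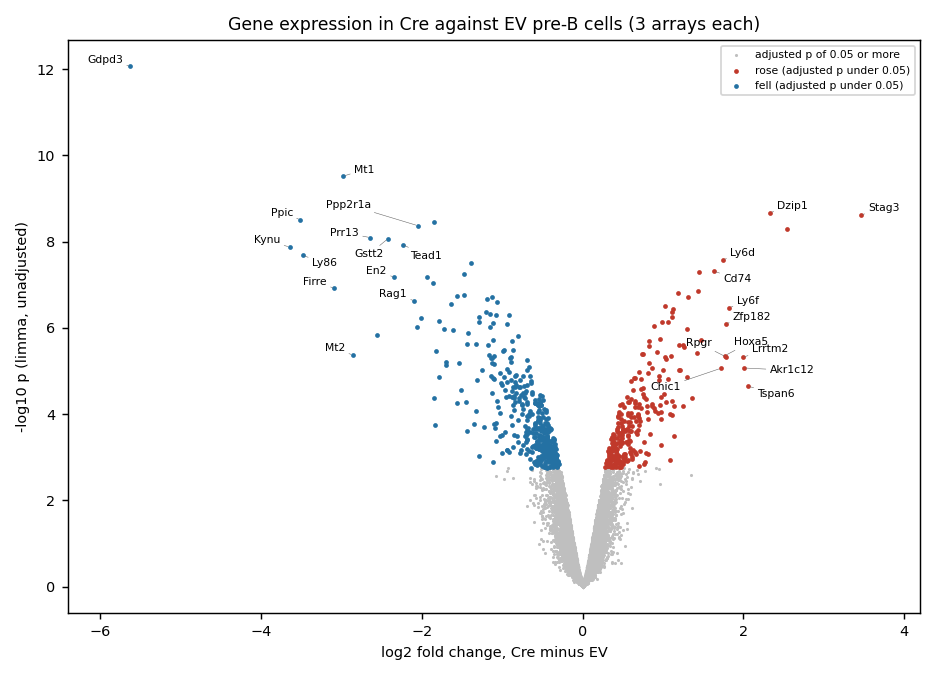
Each point is 1 of 19733 genes, with the log2 change (Cre minus EV, 3 arrays each) on the x axis and -log10 of the unadjusted limma p on the y axis; red points rose and blue points fell at an adjusted p below 0.05. Gdpd3 lies farthest left at -5.62, Stag3 farthest right at 3.46, and Ppp2r1a at -2.05 lies among the genes of smallest p.

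Most glycolytic genes measured fell in the Cre cells. Of 22 measured genes of glycolysis and lactate transport, 13 fell, 0 rose and 9 did not pass (adjusted over the list alone, 16 fell and 1 rose), with a median change of -0.43. Aldoc, an aldolase, fell from 7.43 ± 0.07 to 5.42 ± 0.28 (SD, n = 3), 4.04-fold. Slc16a3, a lactate exporter, fell 2.15-fold, Aldoa, the main aldolase, 1.85-fold, and Slc2a1, the glucose transporter GLUT1, 1.45-fold. Among the other falls were Pdk1, which restrains pyruvate dehydrogenase (2.13-fold), Pfkl of the committing step (1.68-fold), Tpi1 (1.66-fold), and Ldha, which makes lactate (1.35-fold). The camera adjusted p was 1.375e-11 with the preset correlation, while the adjusted p was 0.147 with an estimated correlation. Pdk1 and Ldha lost the call without Cre replicate 2, EV replicate 1 or EV replicate 2, with a highest adjusted p of 0.0574 and 0.0546 in limma.

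Targets of hypoxia-inducible factor (HIF) also fell more often than they rose. Of 24 measured, 10 fell, 2 rose and 12 did not pass (adjusted over the list alone, 13 fell and 4 rose), with a median of -0.33. Ankrd37 fell 2.45-fold, from 7.84 ± 0.09 to 6.55 ± 0.13 (SD, n = 3), and the mitophagy receptors Bnip3 and Bnip3l fell 1.97-fold and 1.67-fold. Ak4, a mitochondrial adenylate kinase, fell 3.56-fold, with a wide spread in Cre (4.77 ± 0.63). Against the list's direction, the lipid droplet protein Plin2 rose 1.63-fold and Ddit4, an inhibitor of mTORC1, 1.41-fold. The camera adjusted p was 0.000248, and the adjusted p was 0.254 with an estimated correlation. With the genes that are also in the glycolysis list left out, a choice made after the results were seen, 21 hypoxia genes had a median of -0.28 (camera adjusted p = 0.00133; unadjusted p = 0.0551 with an estimated correlation). The call of Ak4 was lost without Cre replicate 2 or EV replicate 1 (highest adjusted p = 0.0545), and that of Ddit4 in 5 of the 6 fits with 1 array left out (highest 0.0897).

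**Figure D2:**
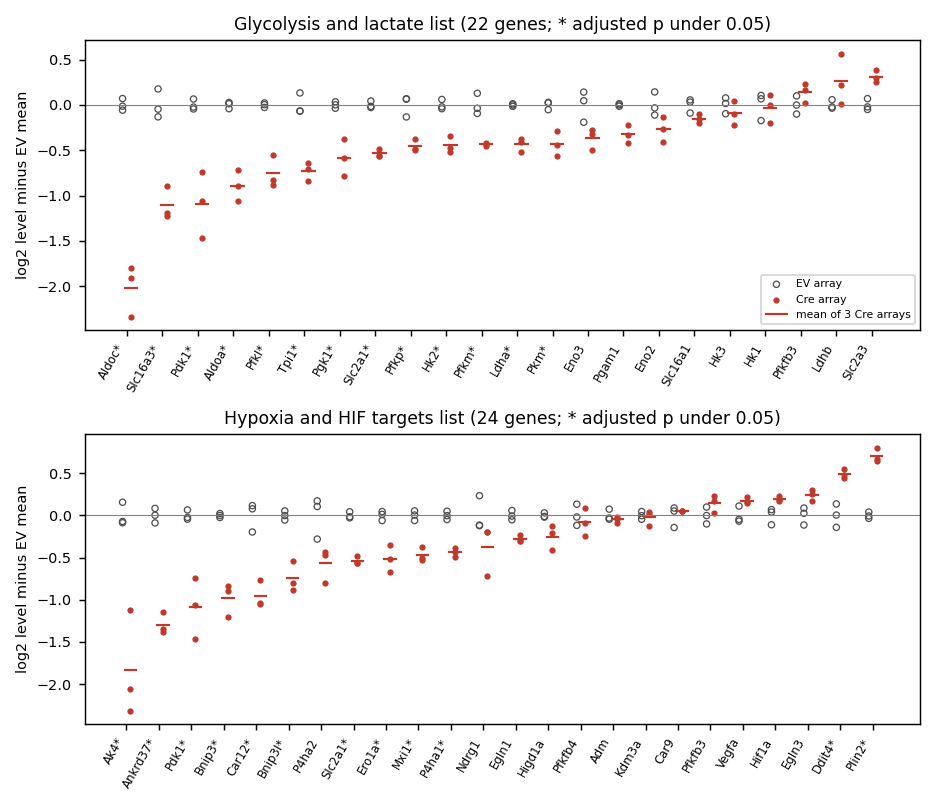
Log2 level minus the gene's EV mean (y axis) for each measured member of the glycolysis and lactate list (22 genes) and of the hypoxia and HIF targets list (24 genes); open points are the 3 EV arrays, filled points the 3 Cre arrays, bars the Cre means, and stars mark an adjusted p below 0.05. Aldoc and Ak4 lie lowest, at mean changes of -2.01 and -1.83, and Plin2 highest, at 0.71.

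Few genes on the antioxidant list passed the test, and those that did were lower in Cre. Of 37 measured antioxidant genes and targets of the redox regulator NRF2, 3 fell and 0 rose (adjusted over the list alone, 6 fell and 3 rose). Gsr, which regenerates reduced glutathione, fell 1.45-fold, catalase (Cat) 1.27-fold and the microsomal glutathione transferase Mgst1 2.44-fold. Nqo1, a typical NRF2 target, was dim in both groups, at 3.39 ± 0.13 in EV and 3.22 ± 0.18 in Cre (SD, n = 3). The list's camera adjusted p was 0.756, with a median of 0.03 and a mean of -0.06. In the pentose phosphate pathway, which supplies NADPH, 2 of 11 measured genes rose and 0 fell, also when adjusted over the list alone: Taldo1 rose 1.28-fold and Rpia 1.34-fold, both of the non-oxidative branch. Pgd, an NADPH-producing enzyme, differed by -0.02 (SE 0.06) and Tkt, a transketolase, by -0.13 (SE 0.06), and neither passed. G6pdx, a further entry of this list, was not matched to a tested gene, so its change is not known here. The list did not move in camera (adjusted p = 0.101), while fry's directional test gave it an adjusted p of 0.0459. The calls of Taldo1 and Cat were lost in all 6 fits with 1 array left out (highest adjusted p 0.0788 and 0.117 in limma), and those of Rpia and Mgst1 in 5 of 6 (highest 0.104 and 0.111).

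Few mitochondrial genes passed. None of 27 genes of oxidative phosphorylation did, by either adjustment (camera adjusted p = 0.788). Ndufa4 differed by 0.16 (SE 0.06) and Ndufs7 by -0.16 (SE 0.07). Of 24 genes of the TCA cycle, 2 fell and 0 rose, also when adjusted over the list alone: Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, 1.61-fold (from 9.03 ± 0.03 to 8.34 ± 0.05; SD, n = 3), and Pdha1, of pyruvate dehydrogenase, 1.30-fold. That list did not move (camera adjusted p = 0.142), and Pdha1 lost its call in all 6 fits with 1 array left out (highest adjusted p = 0.121).

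Lipid synthesis lists moved in opposite directions with camera's preset correlation. In fatty acid synthesis 2 of 17 genes fell and 0 rose by either adjustment, both of them desaturases that make monounsaturated fatty acids, and the list moved down (camera adjusted p = 0.00272; adjusted p = 0.147 with an estimated correlation). Scd1 fell 3.61-fold, from 9.69 ± 0.06 to 7.84 ± 0.01 (SD, n = 3), and Scd2 1.30-fold, the latter lost in all 6 fits with 1 array left out (highest adjusted p = 0.109). Without the pair, which was picked because it passed, the other 15 genes had a median of -0.11 and a camera adjusted p of 0.0925. For cholesterol biosynthesis, 0 of 19 genes passed over all genes and 4 rose when adjusted over the list alone. Its camera adjusted p was 0.00953, with a median of 0.09, and the adjusted p was 0.435 with an estimated correlation. Idi1 differed by 0.34 (SE 0.08) and Nsdhl by 0.28 (SE 0.06), and the list's call was lost without EV replicate 1 (adjusted p = 0.140).

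Genes that mark B cell stages shifted in both directions. Of 27 markers of mature and germinal centre B cells, 5 rose and 0 fell (adjusted over the list alone, 6 rose and 2 fell). Cd74 rose 3.11-fold, from 5.96 ± 0.09 to 7.59 ± 0.09 (SD, n = 3). Ms4a1, which encodes CD20, rose 2.69-fold from a dim 3.46, Cd72, an inhibitory co-receptor, 2.08-fold, and Cxcr5, the follicle-homing receptor, 1.94-fold. Spib, a transcription factor, rose 1.40-fold, a call lost without Cre replicate 1, Cre replicate 2, EV replicate 2 or EV replicate 3 (highest adjusted p = 0.068). The list moved up (camera adjusted p = 0.00133; adjusted p = 0.147 with an estimated correlation), while the MHC class II gene H2-Aa differed by 0.10 and Ighm by -0.53, and the 22 members that did not pass had a median of 0.06. Of 24 markers of pre-B and early B cells, 4 fell and 0 rose (adjusted over the list alone, 6 fell and 1 rose), and the list did not move (camera adjusted p = 0.338). Rag1 fell from 8.82 ± 0.08 to 6.72 ± 0.25, and its partner Rag2 fell 3.59-fold. Dntt, which adds nucleotides at V(D)J joints, fell 1.39-fold and Sox4 1.24-fold. Vpreb1, of the surrogate light chain, read 11.85 in EV and 11.88 in Cre, and the IL-7 receptor chain Il7r differed by -0.12 (SE 0.06). Dntt lost its call in 5 of the 6 fits with 1 array left out (highest adjusted p = 0.108) and Sox4 in all 6 (highest 0.147).

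Several genes of B cell receptor signalling rose. Of 26 measured genes of the pre-BCR and BCR pathway, 5 rose and 0 fell (adjusted over the list alone, 6 rose). Bank1, a B cell scaffold, rose 2.19-fold and Pik3ap1, which recruits PI3 kinase, 1.68-fold. Dok3, an inhibitory adaptor, rose 1.30-fold, Plcg2 1.29-fold and Vav2 1.27-fold. The list moved up (camera adjusted p = 0.00248; adjusted p = 0.147 with an estimated correlation). Dok3 and Plcg2 each lost the call in 5 of the 6 fits with 1 array left out (highest adjusted p 0.0737 and 0.0944 in limma), and Vav2 in all 6 (0.161). Targets of FOXO transcription factors moved down with the preset correlation (camera adjusted p = 0.0187; adjusted p = 0.270 with an estimated correlation), with 3 of 26 fallen (5 when adjusted over the list alone; 0 rose by either) and a median of -0.09. The 3 were Rag1, Rag2 and Insr, the insulin receptor, which fell 1.48-fold. Camera's adjusted p for this list was 0.180 without Rag1 and Rag2, picked because they passed, and 0.0626 without EV replicate 2.

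Genes that set glucose supply in B cells, and their B lineage regulators, formed a mixed list of 17 in which 5 fell and 1 rose (adjusted over the list alone, 6 fell and 4 rose). Txnip, which limits glucose uptake, fell 1.64-fold, Hk2, a hexokinase, 1.36-fold and Igf1r 1.40-fold, beside Slc2a1 and Insr, while Slc2a6, a glucose transporter, rose 1.36-fold. The list did not move (camera adjusted p = 0.704), and its median was 0.01 with a mean of -0.08. Txnip lost its call without Cre replicate 2, EV replicate 1 or EV replicate 2 (highest adjusted p = 0.072 in limma). Hk2 (highest 0.0741) and Slc2a6 (0.134) lost it in 5 of the 6 fits with 1 array left out, and Igf1r (0.108) in all 6.

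A few genes of mitosis rose by small amounts. Of 35 G2/M genes, 3 rose and 0 fell over all genes, 9 rose when adjusted over the list alone, and 29 had a positive change, with a median of 0.11. Kif20a rose 1.29-fold, Cdc20, an activator of the anaphase-promoting complex, 1.27-fold and Kif23 1.27-fold. The list moved up (camera adjusted p = 1.724e-06; adjusted p = 0.147 with an estimated correlation). Kif20a lost the call in 5 of the 6 fits with 1 array left out (highest adjusted p = 0.107), and Cdc20 and Kif23 in all 6 (0.112 and 0.123). None of 35 S phase genes passed, by either adjustment (camera adjusted p = 0.0925). Ccne2 differed by 0.22 (SE 0.06) and Ccne1 by 0.23 (SE 0.08).

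Some cell-cycle inhibitors rose. Of 19 genes of cell-cycle inhibition and senescence, 4 rose and 0 fell (adjusted over the list alone, 7 rose and 2 fell). Gadd45b rose 1.62-fold, Cdkn2c, the Cdk4 and Cdk6 inhibitor p18, 1.38-fold, the anti-proliferative gene Btg2 1.36-fold, and Ccng1, a p53 target, 1.36-fold (from 10.10 ± 0.004 to 10.54 ± 0.05; SD, n = 3). The list's camera adjusted p was 0.00248 (adjusted p = 0.147 with an estimated correlation). Cdkn2c lost its call in 5 of the 6 fits with 1 array left out (highest adjusted p = 0.0815). Of 26 p53 targets, 2 rose and 0 fell (adjusted over the list alone, 7 rose and 3 fell). The 2 were Btg2 and Ccng1, which are shared with the inhibitor list. The p53 list moved up with a median of 0.14 (camera adjusted p = 0.00248, and 0.347 with an estimated correlation). Its entries Trp53, Cdkn1a, Bax and Gdf15 were not matched to a tested gene, so neither list holds a value for Cdkn1a.

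Myc fell 2.00-fold in the Cre cells, from 11.31 ± 0.08 to 10.31 ± 0.35 (SD, n = 3). Of 30 genes of Myc and ribosome biogenesis, Myc and Nop16 (1.35-fold lower) fell and 0 rose, also when adjusted over the list alone. The list moved down with a median of -0.11 (camera adjusted p = 0.00133; adjusted p = 0.391 with an estimated correlation), and 0.00259 was the adjusted p without Myc. None of 20 ribosomal proteins passed by either adjustment, and 19 of them had a negative change, with a median of -0.06. Rps3 differed by -0.14 (SE 0.06) and Rpl5 by -0.12 (SE 0.06). Camera gave the ribosomal list an adjusted p of 0.0327, which went to 0.270 with an estimated correlation, to 0.375 after quantile normalization again, and to 0.0588 to 0.127 in 5 of the 6 fits with 1 array left out, all but that without EV replicate 1. Myc lost its call without Cre replicate 1, EV replicate 1, EV replicate 2 or EV replicate 3 (highest adjusted p = 0.0662) and Nop16 in all 6 (highest 0.0998).

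The JAK-STAT5 and ERK lists, which cover 2 arms of signalling downstream of BCR-ABL1, did not move. Of 20 JAK-STAT5 targets, 2 fell and 1 rose (3 each when adjusted over the list alone). Ccnd3, cyclin D3, fell 1.32-fold beside Myc, and Socs2, a feedback inhibitor, rose 1.26-fold (camera adjusted p = 0.478). Of 27 genes of ERK feedback and the immediate early response, 3 fell and 0 rose (adjusted over the list alone, 8 fell and 4 rose): Myc, the ERK pathway inhibitors Dusp4 (1.36-fold) and Spred1 (1.26-fold) (camera adjusted p = 0.063). Ccnd3 lost its call without Cre replicate 2, Cre replicate 3, EV replicate 2 or EV replicate 3 (highest adjusted p = 0.063 in limma), Dusp4 in 5 of the 6 fits with 1 array left out (0.0659), and Socs2 and Spred1 in all 6 (0.148 and 0.129).

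Of the genes that control cell death, the survival gene Bcl2 fell 1.73-fold, from 8.54 ± 0.10 to 7.74 ± 0.15 (SD, n = 3), and Casp6, an executioner caspase, 1.66-fold. Each was the 1 member of its list that passed, among 14 anti-apoptotic genes (camera adjusted p = 0.375) and 19 pro-apoptotic genes and death receptors (camera adjusted p = 0.2998). Bcl2l1, which encodes BCL-XL, differed by 0.31 (SE 0.07; limma adjusted p = 0.0533), and Endog by -0.34 (SE 0.08; adjusted p = 0.0639). Adjusted over the list alone, 2 anti-apoptotic genes fell and 1 rose, and 2 pro-apoptotic genes fell and 2 rose.

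Among stress lists, the interferon response moved up with a median of 0.13 (camera adjusted p = 0.00208; adjusted p = 0.147 with an estimated correlation). Of its 28 genes, 2 rose, Irf1 and Isg20 (1.32-fold and 1.33-fold), and 1 fell, Ifit2 (1.38-fold); adjusted over the list alone, 3 rose and 1 fell. Of 33 genes of the unfolded protein and integrated stress response, 3 rose and 2 fell (5 each when adjusted over the list alone), and the list did not move (camera adjusted p = 0.935; median -0.02, mean 0.003). Edem1, of protein degradation from the endoplasmic reticulum, rose 1.85-fold and the stress sensor Atf6 1.35-fold, beside Ddit4, while Ero1a, an oxidase of protein folding, fell 1.43-fold and Atf5 1.26-fold. Hexa, a lysosomal hexosaminidase, rose 2.29-fold (from 4.62 ± 0.09 to 5.82 ± 0.16; SD, n = 3), and with Bnip3 it made 1 rise and 1 fall among 28 lysosome and autophagy genes (camera adjusted p = 0.375; 3 rose and 2 fell over the list alone). Irf1 and Atf5 lost the call in all 6 fits with 1 array left out (highest adjusted p 0.0958 and 0.119 in limma), Isg20, Ifit2 and Ero1a in 5 of 6 (0.0991, 0.115 and 0.0911), and Atf6 without Cre replicate 2, Cre replicate 3 or EV replicate 3 (0.0566).

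Markers of other cell types showed few changes. Of 30 myeloid markers, Spi1, which B cells also express, rose 1.30-fold (camera adjusted p = 0.756), and Cd68 differed by -0.36 (SE 0.08). Of 21 T and NK cell markers, the co-stimulatory receptor Cd28 rose 2.30-fold and Cd2 fell 1.36-fold (camera adjusted p = 0.948; median -0.02, mean 0.03). Of 16 erythroid and megakaryocyte markers, the carbonic anhydrase Car2 fell 1.71-fold (camera adjusted p = 0.478), and Epb42 differed by -0.16 (SE 0.08). None of 23 stromal markers passed (camera adjusted p = 0.948). Vim differed by 0.20 (SE 0.07) and Cxcl12 by -0.21 (SE 0.07). Adjusted over the list alone, 2 myeloid markers rose and 1 fell, and the counts of the other 3 lists were as over all genes. Spi1 lost its call in 5 of the 6 fits with 1 array left out (highest adjusted p = 0.0923 in limma), and Cd2 without Cre replicate 2, Cre replicate 3, EV replicate 2 or EV replicate 3 (0.0923).

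The remaining lists did not move. None of 23 NF-kB targets passed by either adjustment (camera adjusted p = 0.151), with Tnf at 0.33 (SE 0.08) and Nfkbiz at 0.28 (SE 0.07). None of 12 heat shock genes passed by either adjustment (camera adjusted p = 0.756), with Hspa8 at -0.15 (SE 0.06) and Hspd1 at -0.12 (SE 0.06). Of 28 adhesion and cytoskeleton genes, Tpm1 fell 1.25-fold and the integrin Itga4 1.30-fold, also when adjusted over the list alone (camera adjusted p = 0.2998). Of 25 DNA repair genes, Apex1 fell 1.29-fold (adjusted over the list alone, 1 fell and 1 rose), and Lig4 differed by 0.36 (SE 0.08), with a camera adjusted p of 0.948, a median of 0.01 and a mean of -0.01. Of 13 housekeeping genes, the glycolytic enzyme Pgk1 fell 1.498-fold, by either adjustment, and Ywhaz differed by 0.18 (SE 0.07), with a camera adjusted p of 0.704, a median of 0.003 and a mean of -0.01. Tpm1, Itga4 and Apex1 lost the call in all 6 fits with 1 array left out (highest adjusted p 0.137, 0.126 and 0.111 in limma), and Pgk1 in 5 of 6 (0.0913). Of all 37 lists, 13 moved with the preset correlation (7 up, 6 down). With an estimated correlation 0 of the 37 moved (smallest adjusted p 0.147), and 7 had an unadjusted p below 0.05.

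**Figure D3:**
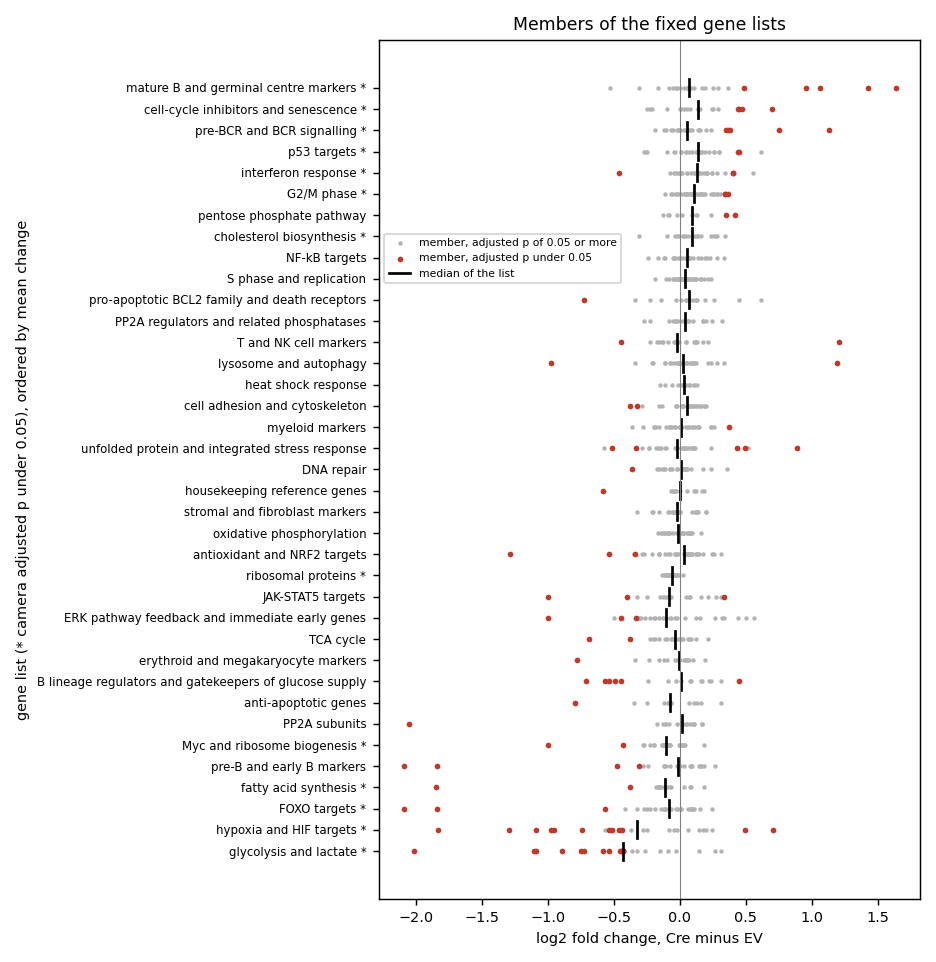
Log2 change (Cre minus EV, 3 arrays each; x axis) of each measured member of the 37 lists (y axis, ordered by mean change); red points passed the limma test at an adjusted p below 0.05, black bars are list medians, and stars mark the 13 lists that moved in camera. Glycolysis, at a median of -0.43, and hypoxia, at -0.33, lie lowest.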

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

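Probes outside the main test also carried signal that differed between the groups. In the fit over all 25006 probes, a setting chosen beforehand, 15 of the 1521 probes assigned to several genes rose in Cre at a limma adjusted p below 0.05 and 21 fell, with changes between -2.59 and 1.55 on the log2 scale. Of the 2018 probes with no assigned gene, 28 rose and 28 fell, with changes between -1.16 and 1.98. Their genes were not named here, and no explanation was tested.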

How the results depend on the processing

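The reduced lists were tested only after the results were seen; every other setting was chosen beforehand. No gene followed through these settings reversed its change, and no list that moved reversed its direction. H2-Aa, H2-Ab1, H2-Eb1, Cr2, Fcer2a and Ighm were not followed through them. Ppp2r1a stayed between -2.107 and -2.011 and passed throughout. The 689 changed genes became 1558 with trend and robust moderation, 1295 with the lowest 50% by mean level left out, 148 with ordinary t statistics, 209 against a 1.2-fold change, 128 at 2-fold or more, and 362 to 424 with 1 array left out; 6 other settings with no replicate block gave 688 to 940. Fewer arrays enter when 1 is left out, and thresholds on the fold are stricter by construction. Leaving out dim genes lowers the number of genes tested and also refits limma's moderation. With the lowest 50% left out, Ppp2r1a kept its change of -2.052, while its limma adjusted p went from 1.203e-05 to 4.821e-07. The cause of the higher counts was not tested for leaving out dim genes or for the moderation settings. The share that fell was 61.2%, and 56.2% to 64.7% in the alternatives. Of the 105 named genes that passed, Ppp2r1a apart, 32 passed in every alternative in which they were followed. Named genes were not followed over all probes, at the 2-fold minimum or against a 1.2-fold change. Those left out as dim were not tested in that setting. Another 17 passed in no fit with 1 array left out, and ordinary t statistics lost 70. Each kept at least 76.3% of its log2 change with 1 array left out.

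The 13 lists that moved became 0 with an estimated correlation and 35 in fry's mixed test, which asks for change in either direction; the cause was not tested for the former. The other settings gave 11 to 16. The 16 came from fry's directional test, which also called lists that camera had not. These were PP2A subunits (fry adjusted p = 0.00824), erythroid and megakaryocyte markers (0.00866), pre-B and early B markers (0.0178) and the pentose phosphate pathway (0.0459). Apart from the estimated correlation, 10 lists moved in each setting chosen beforehand. FOXO targets lost the call without EV replicate 2 (adjusted p = 0.0626) and with the lowest 50% left out (0.0823), cholesterol biosynthesis without EV replicate 1 (0.140) and in fry's directional test (0.0627), and ribosomal proteins in several settings. FOXO targets without Rag1 and Rag2 (0.180), fatty acid synthesis without Scd1 and Scd2 (0.0925) and mature B markers without the 5 that passed (0.456) lost the call, which follows at least in part from leaving out members because they passed. Camera was not run on ordinary t statistics.

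With the repeat number as a replicate block, 425 genes and 12 lists passed, and 403 of those genes were among the 689. Deviations of same-numbered arrays from their group means correlated at 0.009, -0.012 and 0.03, so the numbers did not pair the arrays. Signal over background limits dim genes, whose changes are understated.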

Other observations

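Tests in this part were chosen after the results were seen, except the counts over other splits of the arrays.

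Several gene families outside the fixed lists rose in the Cre cells. Among 1710 tests of families named by a shared symbol prefix and a direction, 3 passed Benjamini-Hochberg adjustment. In the Hoxa cluster, whose homeobox genes are active in early blood progenitors, 5 of 10 genes rose (adjusted p = 8.91e-05): Hoxa5 by 1.77 (SE 0.16), Hoxa7 by 1.02 (SE 0.12), Hoxa3 by 0.56 (SE 0.08), Hoxa6 by 0.53 (SE 0.09) and Hoxa4 by 0.44 (SE 0.07). Of 5 Slamf receptors, which sit on the surface of blood cells, 3 rose (adjusted p = 0.0137): Slamf7 1.82-fold, Slamf6 1.77-fold and Slamf1 1.53-fold. Of 20 Snora genes, small nucleolar RNAs that guide pseudouridylation, 7 rose (adjusted p = 8.75e-06), with Snora20 5.82-fold higher and Snora75 2.17-fold higher. The family test treats genes as independent. Neighbouring genes of the Hoxa cluster are not independent, nor may be the 3 Slamf genes, all on chromosome 1. Whether the Snora genes vary together as a class was not tested. The p of each of these families can therefore overstate the evidence. With 1 array left out Hoxa4 lost its limma call without any 1 of the Cre arrays or EV replicate 2 (highest adjusted p = 0.0634), Hoxa6 in 5 of the 6 fits (0.0745), and Slamf1 in 5 of the 6 (0.124).

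The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 689 genes in limma and the highest of the others 1. For lists the real split gave 13 and the highest of the others 5. In both counts the real split was the 1 split with a result as large.

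The fall of glycolysis and hypoxia genes was set against a shift of whole arrays left by the normalization. None of 10000 random lists matched on mean level fell as far (lowest median -0.145, against -0.433 for glycolysis). Genes of like level thus did not share the fall, as they would under a shift of whole arrays. Quantile normalization keeps such medians near 0, and both lists were picked for their fall, so the count itself is no test. A change of the whole transcriptome would be hidden. Glycolysis and hypoxia kept their calls at the preset correlation after quantile normalization again (medians -0.414 and -0.311) and median centring. Each of these settings cost the ribosomal list its call. As the deposited values were already quantile-normalized with near-equal medians, both settings could move values only a little and lend no support. With an estimated correlation neither list was called (camera adjusted p = 0.147 for glycolysis and 0.254 for hypoxia). The 21 hypoxia genes outside the glycolysis list had a median of -0.279, so the 3 shared genes do not carry the fall. As these 21 are most of the 24 whose fall raised the question, they do not test whether HIF activity was lower in the Cre cultures. That remains a candidate explanation, whether through the deletion, Cre itself or oxygen in the cultures, which was not analysed here, and Plin2 and Ddit4 rose.

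The rise of 5 mature B markers beside the fall of Rag1 and Rag2 was set against admixed cells. Among 9 abundant mature B transcripts that were dim in EV (below 6), so that a small share would show, the 4 markers that passed rose (Cd74, Cd72, Cxcr5 and Ms4a1), while H2-Aa differed by 0.10, H2-Ab1 by -0.08, H2-Eb1 by 0.09, Cr2 by 0.07 and Fcer2a by 0.17. The median of the 9, 0.167 (SD 0.665) against 1.059 for the passed markers, tests nothing, as the 4 were included because they passed. Mature B cells would bring all 9, so the flat transcripts argue against such cells as the source. This holds unless the probes of the flat ones, from 3.09 (H2-Aa) to 4.97 (H2-Eb1) in EV, respond poorly. Of 89 measured markers of myeloid, T, NK, erythroid and stromal cells 2.25% rose, a larger share than the 267 of all 19733 genes. None of their lists moved, so an admixture large enough to raise such a list as a whole was not seen. A small share of a single cell type need not move a list and is not excluded. A change of state in the pre-B cells themselves may remain as a hypothesis and was not tested.

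Several of the largest changes were X-linked. Of all genes that changed and read at least 5 in 1 group, 25 of 608 were X-linked (4.1%, against 2.8% of the others), and of those at least 2-fold, 12 of 113 (10.6%). Of 20 that also read below 4.5 in the other group, 25% were, against 309 of 10833 other genes. Of these, Tspan6, Rpgr, Zfp182 and Chic1 rose and Cask fell. In the larger sets falls outnumbered rises: 8 X-linked genes rose and 17 fell among all that changed. Among those at least 2-fold, 5 rose and 7 fell, with Firre among the falls. All of these sets hold the genes that prompted the count, so the shares describe them and test nothing. Pools of different clones in the groups may be a candidate explanation and stay open, as does an effect of the deletion or of Cre itself. Xist differed by -0.05 (11.03 in EV, 10.98 in Cre), and the smallest adjusted p of a Y-linked gene was 0.16 in limma, which argues against a difference in sex.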
